A study of Homo sapiens with 18 samples.

How the data were processed

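The deposited data were 18 single-cell RNA libraries from human lung tissue or bronchoalveolar lavage (BAL, cells washed from the airspaces). Per the labels, they came from normal lungs or from lungs with idiopathic pulmonary fibrosis (IPF, a progressive scarring disease of the lung). Per the labels' protocols, lung pieces were diced, digested with collagenase and DNase, filtered and loaded for droplet capture with 10x 3′ chemistry, version 1 or version 2. The files are deposited as 1 gene-by-barcode matrix per library. Their values are raw counts of unique molecular identifiers (UMIs), deposited without normalization, as shown by whole numbers whose totals differ between libraries. Reads had been processed with bcl2fastq and Cell Ranger 2.0 against GRCh38, per the submitters' processing notes, which also name Seurat 2.3.4. No deposited file gave cell types, so these were rebuilt here, and a difference from the study may come from the rebuilt names.

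Total depth ranged from 5746335 to 49509942 UMIs per library. Gene tables listed 33694 genes in 17 libraries and 33538 in the library of fresh BAL cells. Cells were called on all listed genes. After that, 106 genes (Y-linked genes, XIST and TSIX) were removed from every later step. Clustering used genes among the 32991 identifiers present in both tables, and all sums and tests used every remaining gene. Coordinates and gene types came from GENCODE release 29 on GRCh38, in which 33132 identifiers matched. A barcode was called a cell with at least 1000 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. This gave 55364 cells. The called cells held 63.1% to 92.5% of each library's UMIs, and their median per library was 2082 to 10479 UMIs. Doublets were scored within each library by Scrublet as implemented in scanpy 1.11.5, with 20 principal components. In place of its score threshold, the highest scoring cells of each library were removed, a share of 0.8% for every 1000 cells called. This took out 1660 cells after clustering and left 53704.

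Counts were scaled to 10000 per cell and log transformed for clustering with scanpy 1.11.5 and anndata 0.12.19. The 2000 most variable genes, without immunoglobulin and T cell receptor genes, gave 30 principal components and 15 neighbours per cell. The neighbours were found by brute force with scikit-learn 1.9.0. Leiden clustering (igraph 0.11.9) at resolution 1.5 gave 37 clusters, with no integration across libraries. Clusters were named "X-like" from markers of 21 cell types fixed before the data were examined. The mean log2 fold of the leading type's markers against all other cells had to be above 0.5 and at least 0.3 above that of the next type, with at least 3 markers each detected in 10% of the cells. A cluster was also left unnamed when its 10 leading genes held more markers of another type, or when it was shallow with no own marker among them. The lead of 0.3, and the rule that only a type with 3 detected markers could lead, were set after the clusters were seen. The second of these gave cluster 17, which cell cycle genes led and which held 646 cells over all libraries, its macrophage-like name. The results on thinned cells were therefore also computed without that cluster. The rules left 3 clusters unnamed, in which markers of 2 types led alike. Those clusters held 5.72% of the IPF lower lobe cells, 2.40% of the IPF upper lobe cells and 0.600% of the normal cells compared.

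The comparison named in the series' design text was followed: the 3 normal version 2 libraries of mixed lobes, the 5 IPF lower lobe libraries and the 3 IPF upper lobe libraries. That text gives 3 IPF lungs, and the labels tie no library to a lung. The 5 lower lobe libraries therefore came from 3 lungs, and p-values over them as 5 samples are too small. Lower and upper lobe libraries also share lungs, which no model here could use. The normal libraries compared were of mixed lobes, so a test of 1 IPF lobe against them cannot tell lobe from disease. The remaining 7 libraries entered none of the comparisons reported, and the single-lobe normal libraries were added to the normal group only as an alternative: 3 mixed-lobe normal libraries on version 1, 1 normal lower lobe library, 1 normal upper lobe library, and 1 frozen and 1 fresh normal BAL library. They are reported as values. The design text gives 3 normal lungs compared and 1 further lung on version 2, so the 5 normal lung libraries on version 2 came from 4 lungs. It gives 2 lungs on version 1, so the 3 libraries on version 1 came from 2 lungs.

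UMIs were summed per library and cell class where a library held at least 20 cells of the class. Cells were never used as replicates in a test between groups. The classes tested were macrophage-like cells and the next 4 classes by number of cells: T-like, vascular endothelial-like, monocyte-like and fibroblast-like. Summed counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, in 1 fit over the 3 groups. A gene passed with a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene below comes from that test unless another tool is named. The SE given with a log2 change is the size of the change divided by the square root of its F value. It therefore restates the test and is no separate estimate of spread. Levels are in CPM, the class's summed UMIs as scaled by edgeR's cpm function. The test was also run on simulated data with 200 genes changed, drawn from the pooled gene means, the gene dispersions and the library sizes of the real fit. For macrophage-like cells it recovered 17.5% of 2-fold and 71.6% of 4-fold changes in lower lobe against normal, over 12281 genes. The shares were 15.2% and 76.8% for upper lobe against normal over 12388 genes, and 21.0% and 78.0% for lower against upper lobe over 12336 genes. For 4-fold changes against normal in the lower and upper lobe, recovery was 92.1% (6185 genes) and 89.7% (6183 genes) in T-like cells, and 49.5% (10275 genes) and 36.8% (10306 genes) in vascular endothelial-like cells. It was 90.6% (7507 genes) and 80.6% (7499 genes) in monocyte-like cells, and 66.3% (8924 genes) and 46.9% (8936 genes) in fibroblast-like cells. Of the genes called in each simulation, 1.41% to 8.80% had not been changed. The simulation drew every library independently and so left out that lower lobe libraries share lungs. Its shares of recovered and false calls may therefore not hold for the real tests with such libraries.

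Gene lists fixed before the data were examined were tested with camera from limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera asks whether a list stands apart from all other genes, and it was repeated with a correlation estimated from the libraries. The fry test asks whether a list's genes move, on balance, in one direction, without comparing them to other genes. Lists for surfactant and for keratins were fixed but not tested, because no epithelial class was among those tested.

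Shares of cells with a transcript, and of cycling cells, were taken after each cell was randomly thinned to 1500 UMIs, and shallower cells were left out. A cycling cell had UMIs of at least 3 of 15 cell cycle genes. Macrophage-like cells of IPF libraries with at least 5 SPP1 UMIs of 1500 (SPP1-high) were compared with those with 0 (SPP1-none) by edgeR on summed thinned counts. The library was a block and SPP1 was left out. On simulated data over 2858 genes this comparison recovered 95.7% of 2-fold and 100% of 4-fold changes, again without the sharing of lungs between libraries. Shares were compared by exact 2-sided permutation tests over libraries. Intervals of single libraries are 95% Clopper-Pearson intervals, and a count of 0 was taken to allow up to 3 counts. Both cover counting error only.

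The genes named were chosen by a rule fixed before the data were examined. In macrophage-like cells it took the 12 largest rises and 8 largest falls against normal, among genes that passed, had a mean log2 level of at least 5 and whose libraries did not overlap between the groups. The numbers were 4 and 4 in other classes, and 10 and 10 for SPP1-high cells. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and HLA genes and markers of other cell types were left out of the rule. It also named 18 macrophage genes in any case and the members of each described list with the smallest p. Alternatives covered DESeq2 1.42.0, RLE scaling, no count filter, other limits on UMIs, mitochondrial share and cells, doublets kept, Leiden resolution 0.7, other control sets, other fits, other depths and each library left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.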

Results

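RNA of single cells was counted in 18 libraries from human lung. The comparisons used 11 libraries on version 2 chemistry: 3 of mixed lobes from normal lungs, 5 of the lower lobe and 3 of the upper lobe from lungs with idiopathic pulmonary fibrosis (IPF). Their depth was 23929856, 29759891 and 29780751 unique molecular identifiers (UMIs) in normal replicates 1 to 3. The IPF lower lobe replicates 1 to 5 had 42321110, 45786307, 37265528, 35529541 and 33406768 UMIs, and the IPF upper lobe replicates 1 to 3 had 49509942, 36389684 and 34534521. These libraries gave 38542 cells, 2107 to 5081 per library. The libraries outside the comparisons were 3 normal version 1 libraries (5746335, 6795014 and 7249459 UMIs), 1 normal lower lobe library (38799311), 1 normal upper lobe library (48055738), and frozen (6736170) and fresh (38258642) cells of normal lavage. No 2 libraries of a group had counts that matched within sampling noise. Lower lobe replicates 1 and 2 (chi-square per degree of freedom 73.2), and 3 and 4 (10.1), differed less from each other than the other lower lobe pairs did (201 to 434), and the labels do not tie libraries to lungs.

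Macrophages, the phagocytes of the airspaces, carried far more SPP1 in the IPF lower lobe than in normal lung, the question the series title raises. SPP1, which encodes the secreted matrix protein osteopontin, rose by a log2 change of 6.03 ± 1.06 (SE; 5 against 3 libraries, adjusted p = 0.00647), from 88.3 ± 64.4 to 5789 ± 3729 CPM (SD). CHI3L1, a chitinase-like secreted protein, rose by 7.14 ± 1.17 (adjusted p = 0.0047), and MMP7, a matrix-cleaving protease, rose by 6.86 ± 1.30 (adjusted p = 0.00844). MERTK, a receptor for the uptake of dying cells, was at 45.5 ± 25.3 against 11.4 ± 15.9 CPM, and its log2 change of 2.02 ± 0.99 did not pass (adjusted p = 0.189). FABP4, a fatty acid carrier of resident alveolar macrophages, was at 482 ± 468 against 3481 ± 2042, and its change of -2.85 ± 0.89 also did not pass (adjusted p = 0.0528). On GRCh38, SPP1 (ENSG00000118785) lies on chromosome 4 from 87975650 to 87983426, and MERTK (ENSG00000153208) on chromosome 2 from 111898479 to 112029561. CHI3L1 (ENSG00000133048) lies on chromosome 1 from 203178931 to 203186749, and MMP7 (ENSG00000137673) on chromosome 11 from 102520508 to 102530753.

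**Figure D1:**
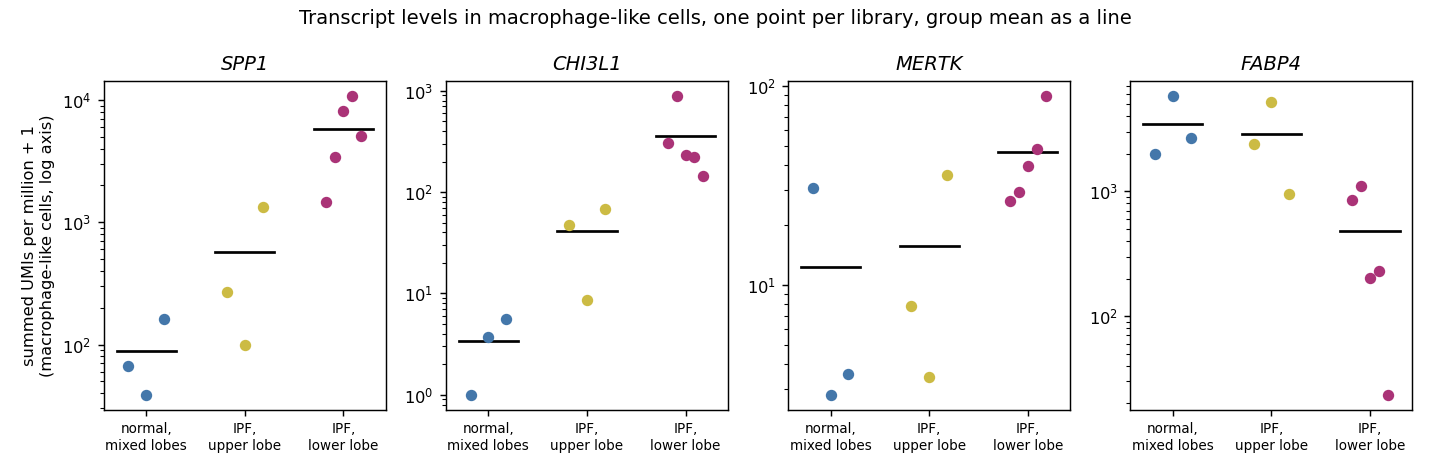
SPP1, CHI3L1, MERTK and FABP4 in macrophage-like cells, as summed CPM plus 1 on a log axis, with 1 point per library and a line at each group's mean. Mean SPP1 was 88.3 in the normal libraries, 5789 in the IPF lower lobe and 570.5 in the IPF upper lobe.

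Other genes that rose in lower lobe macrophage-like cells were CHIT1 (log2 change 6.50), CCL7 (5.15), HS3ST2 (5.04), CD48 (4.33), RARRES1 (4.03), MMP9 (3.95), TDRD3 (3.78), SDS (3.46) and FOLR2 (3.26). The receptor TREM2, which binds lipids, rose by 1.98 ± 0.31 (adjusted p = 0.00424), from 99 ± 27.7 to 392 ± 139 CPM. GPNMB (1.45), LGMN (3.23) and SPARC (2.84) also rose, as did the proliferation genes MKI67 (1.98 ± 0.54, adjusted p = 0.032) and TOP2A (2.26 ± 0.62, adjusted p = 0.0334). Without cluster 17, which cell cycle genes led and whose macrophage-like name came from a rule set after the clusters were seen, MKI67 and TOP2A had too few counts to be tested. The steroid-reducing enzyme AKR1C2 fell by 5.17 ± 1.12 on the log2 scale (adjusted p = 0.0139), followed by CAMP (-4.06), AGRP (-3.47), GLDN (-3.07), FHL1 (-3.04), OASL (-2.69), NHSL2 (-2.63) and RP11-598F7.3 (-2.60). PPARG, a transcription factor of alveolar macrophages, fell by 0.92 ± 0.24 on the log2 scale (adjusted p = 0.0295). INHBA (-2.33, adjusted p = 0.162), MRC1 (-1.02; 0.104), FCN1 (1.32; 0.225), CCL18 (0.41; 0.679), APOE (0.67; 0.445) and MARCO (0.09; 0.861) did not pass.

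Of 24 genes in a list for SPP1/MERTK macrophages, 13 rose, 0 fell and the others did not pass, while adjusted over the list alone 16 rose and 1 fell. The list test gave adjusted p = 6.83e-13, and adjusted p = 0.0833 with an estimated correlation. SPP1 and MERTK come from the series title, which rests on these samples, so this list is not independent evidence. The phagocyte matrix list shares MMP7, MMP9, CTSK, SPARC and SDC2 with it. The lipid handling list shares APOE, APOC1, LPL, LIPA, PLIN2 and FABP5 with it. Results of these lists, here and below, are therefore not separate evidence. Among 29 cell cycle genes 13 rose and 0 fell, such as RRM2 (2.99) and TYMS (2.12), with 20 rising when adjusted over the list alone (list adjusted p = 2e-11, adjusted p = 0.347 with an estimated correlation). Without cluster 17, RRM2 could not be tested and TYMS no longer passed (0.92). Among 22 matrix genes of phagocytes 15 rose and 1 fell, with TGFBI (1.91) and SDC2 (2.64) rising and counts of 16 and 1 adjusted over the list alone (list adjusted p = 3.49e-11, adjusted p = 0.0833 with an estimated correlation). Among 20 genes of resident alveolar macrophages 6 fell and 0 rose, such as CES1 (-1.92) and CD52 (-1.09), and 14 fell adjusted over the list alone (list adjusted p = 3.09e-07, adjusted p = 0.347 with an estimated correlation). Of 18 genes of monocyte-derived macrophages 5 rose and 1 fell, with S100A9 (1.55) and CD14 (2.24) rising and counts of 6 and 1 adjusted over the list alone (list adjusted p = 0.0283, adjusted p = 0.402 with an estimated correlation). Of 18 lipid handling genes 3 rose and 0 fell, such as LIPA (1.07) and SCARB1 (1.49), with 6 and 2 adjusted over the list alone (list adjusted p = 0.0448, adjusted p = 0.433 with an estimated correlation). The lists for profibrotic growth factors (adjusted p = 0.617), cholesterol synthesis (0.205), interferon response (0.51), MHC class II (0.234), inflammatory cytokines (0.161), metallothioneins (0.116), dissociation and heat shock (0.172), unfolded protein response (0.567) and oxidative phosphorylation (0.567) did not pass. For the growth factors the median log2 change was -0.22 while the mean was 0.16 and the test pointed up.

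**Figure D2:**
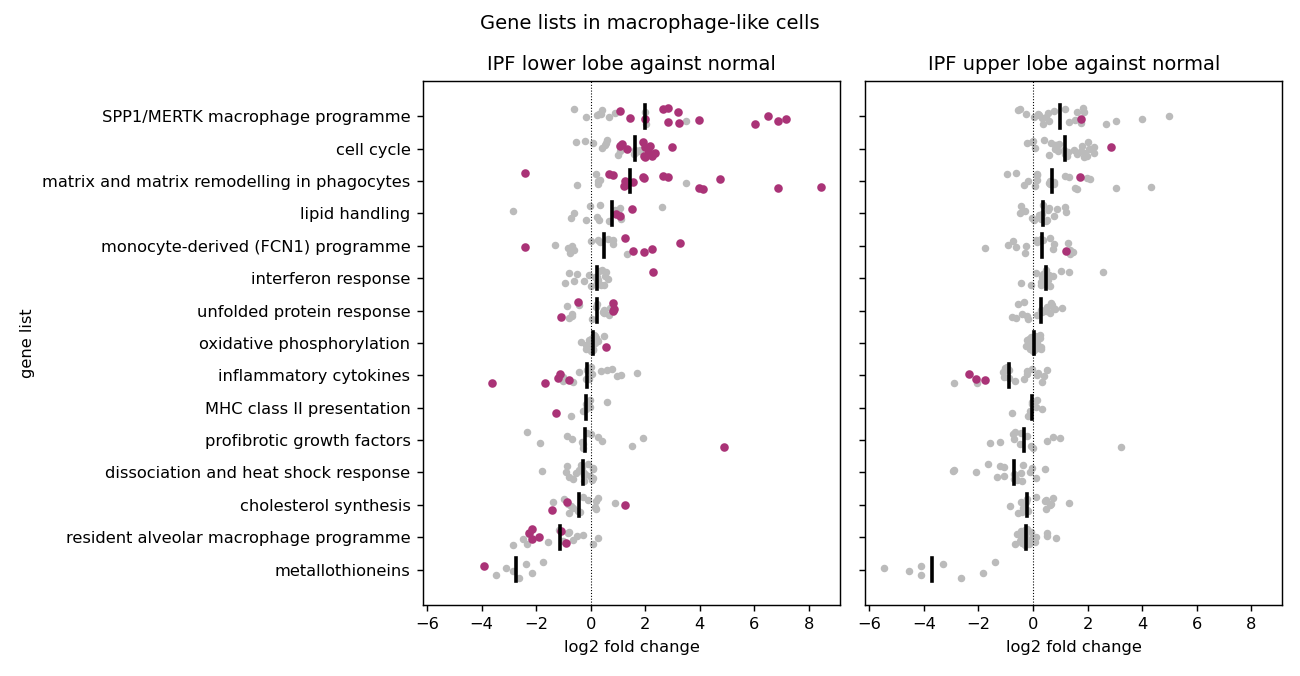
Log2 change of each list's members in macrophage-like cells, IPF lower and upper lobe against normal, with members that passed in purple, the others in grey and a black bar at the median. In the lower lobe the median was 2.00 for the SPP1/MERTK list and -1.12 for the resident macrophage list.

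The edgeR test called 1712 of 12569 genes in this comparison, 880 higher and 832 lower, with 793 to 2226 when 1 library was left out. Choices of 3 of the 5 lower lobe libraries gave 360 to 988. The count with lower lobe libraries 1 and 2, and 3 and 4, summed lay within that lower range. The normal libraries were of mixed lobes, so this test cannot tell lobe from disease. Of the 51 calls of the naming rule, 26 held under every alternative run, among them SPP1, CHI3L1, MMP7 and TREM2. The p-values are too small, because 5 lower lobe libraries came from 3 lungs. The class did not hold the same clusters in both groups: cluster 28 made up 71.1% of the lower lobe macrophage-like cells, while clusters 11 (32.9%), 3 (32.6%) and 5 (21.4%) led in normal lung. Markers of other cell types were also read in these cells: 7 of 9 ciliated, 5 of 8 fibroblast, 3 of 5 secretory, 3 of 4 basal, 3 of 5 plasma, 2 of 8 monocyte and 2 of 3 lymphatic endothelial markers rose, with 1 mast, 1 AT1, 1 smooth muscle or pericyte, 1 T and 1 mesothelial marker. Markers that fell were 3 of 6 for T, 2 of 9 for AT2 and 1 of 3 for AT1 cells. The summed fibroblast markers were at 62.2 against 8.67 CPM, the secretory markers at 497 against 113, the plasma markers at 179 against 10.2 and the monocyte markers at 2014 against 768.

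In macrophage-like cells of the IPF upper lobe, 74 genes passed against normal lung, but 0 in a fit over only these groups and 9 to 226 when 1 library was left out. None of the 23 calls of the naming rule held under every alternative run. TREM2 rose by a log2 change of 1.77 ± 0.33 (3 against 3 libraries, adjusted p = 0.0393), and TGFBI, a secreted matrix adaptor, rose by 1.74 ± 0.19 (adjusted p = 0.00344). The neutrophil attractant CXCL8 fell by 1.75 ± 0.27 on the log2 scale (adjusted p = 0.0197), and CCL20, which attracts lymphocytes, fell by 2.34 ± 0.31 (adjusted p = 0.013), from 451 ± 162 to 89.0 ± 16.3 CPM. SPP1 was at 570.5 ± 674 CPM, and its log2 change of 2.69 ± 0.93 did not pass (adjusted p = 0.162). MERTK (0.38, adjusted p = 0.875), FABP4 (-0.28; 0.905), CHI3L1 (3.98; 0.0887), MKI67 (1.87; 0.119) and TOP2A (1.96; 0.147) did not pass either. TDRD3 (3.17), CD48 (2.55), LILRB4 (2.11), VAMP5 (1.88), IDH2 (1.56), FAIM (1.41), CALM3 (1.27), ACTG1 (1.26), OSCAR (1.19) and SDSL (1.07) rose, and ZNF90 (-2.33), NACA2 (-2.15), NBEAL1 (-2.08), PTPRE (-0.93), CHIC2 (-0.89) and GPBP1 (-0.84) fell. ZNF90, NACA2 and NBEAL1 fell in at least 3 of the 5 classes tested, and each shares sequence with an abundant gene. They were also lower in single-lobe than in mixed-lobe normal macrophage-like cells.

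Inflammatory cytokines fell as a list in the upper lobe (adjusted p = 8.73e-07, adjusted p = 0.0309 with an estimated correlation), with 3 members falling, among them CXCL1 (-2.10), and 7 adjusted over the list alone. The cell cycle list rose (adjusted p = 5.1e-14, adjusted p = 0.205 with an estimated correlation) with 1 member passing, RRM2 (2.86), and 12 adjusted over the list alone. The SPP1/MERTK list rose (1.69e-06, adjusted p = 0.205 with an estimated correlation) with TREM2 passing and 8 adjusted over the list alone. The matrix list rose (3.82e-05, adjusted p = 0.205 with an estimated correlation) with TGFBI passing and 2 adjusted over the list alone. Without a member that passed over all genes, the interferon response list rose (0.00445, adjusted p = 0.588 with an estimated correlation). The metallothionein list (0.0238, adjusted p = 0.588 with an estimated correlation) and the heat shock list (0.000215, adjusted p = 0.205 with an estimated correlation) fell, likewise without such a member. Without normal replicate 2 the metallothionein list pointed up (0.247). The lists for resident (adjusted p = 0.413) and monocyte-derived macrophages (0.0769), growth factors (0.913), lipid handling (0.0766), cholesterol synthesis (0.872), MHC class II (0.716), unfolded protein response (0.159) and oxidative phosphorylation (0.716) did not pass. For cholesterol synthesis the median was -0.21, the mean 0.05 and the test pointed up. Of the genes called, 43 were higher and 31 lower, and clusters 28 (25.9%), 12 (24.5%) and 3 (22.1%) led the class. Monocyte markers were at 1558 against 768 CPM with 1 of 8 rising, and erythroid markers at 126 against 2.98 CPM with 0 of 3 passing.

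Between the lobes of IPF lungs no single gene passed in macrophage-like cells. SPP1 was at 5789 CPM in the lower and 570.5 in the upper lobe, a log2 difference of 3.34 ± 0.92 (5 against 3 libraries, adjusted p = 0.176). The differences of CHI3L1 (3.16, adjusted p = 0.205), SPARC (1.53; 0.171), MERTK (1.65; 0.475) and FABP4 (-2.57; 0.248) did not pass, and CES1, a lipid esterase, had the smallest value (-2.01 ± 0.33; 0.065). The edgeR test called 0 genes, with 1697 at an unadjusted p under 0.05, and DESeq2 called 275. As lists, the SPP1/MERTK genes (adjusted p = 8.16e-09, adjusted p = 0.0971 with an estimated correlation) and matrix genes (6.67e-08, adjusted p = 0.0971 with an estimated correlation) were higher in the lower lobe, with 9 and 10 members higher adjusted over the list alone. Resident macrophage genes were lower (3.76e-10, adjusted p = 0.176 with an estimated correlation), 10 of them adjusted over the list alone. Cytokines (0.000173, adjusted p = 0.0971 with an estimated correlation) and heat shock genes (0.0232, adjusted p = 0.511 with an estimated correlation) were higher in the lower lobe. Cholesterol synthesis (0.0232, adjusted p = 0.657 with an estimated correlation) and interferon genes (0.0213, adjusted p = 0.657 with an estimated correlation) were lower. Lists for the cell cycle (0.338), monocyte-derived macrophages (0.179), growth factors (0.338), lipid handling (0.338), MHC class II (0.265), metallothioneins (0.48), unfolded protein response (0.338) and oxidative phosphorylation (0.75) did not pass. Markers of other cell types also stood apart in these cells, lower against upper lobe: secretory 497 against 157 CPM, plasma 179 against 19.4, fibroblast 62.2 against 17.3, ciliated 57.0 against 10.5 and T 52.5 against 141, and none of them passed. Cluster 28 made up 71.1% of the class in the lower and 25.9% in the upper lobe.

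Cells with an SPP1 transcript made up more of the macrophage-like cells in the IPF lower lobe, a share counted after thinning each cell to 1500 UMIs among cells called from at least 1000 UMIs. The share was 62.4% ± 21 (SD, n = 5) in the lower lobe, 3.32% ± 2.34 (n = 3) in normal lung and 16.2% ± 14.2 (n = 3) in the upper lobe. The exact permutation p was 0.0357 for lower lobe against normal and for lower against upper lobe (adjusted p = 0.107 for both), and 0.2 for upper lobe against normal. The smallest exact p possible is 0.0357 for 5 against 3 libraries and 0.1 for 3 against 3, so none could pass after adjustment. Those with the lower lobe take 5 libraries of 3 lungs as separate and are too small. MERTK was found in 8.07% ± 3.73 of lower lobe, 2.70% ± 3.35 of normal and 2.51% ± 2.56 of upper lobe cells (exact p = 0.107, 1 and 0.0714 in the order above: lower against normal, upper against normal, lower against upper). SPP1 and MERTK were found together in 5.68% ± 2.87, 0.252% ± 0.248 and 1.02% ± 1.21 of cells of the lower lobe, normal lung and the upper lobe, which was not tested. These shares were not set against those expected from each transcript alone, so they do not show a link between SPP1 and MERTK. FABP4 was found in 8.67% ± 8.43 of lower lobe, 58.8% ± 34.1 of normal and 51.1% ± 33.6 of upper lobe cells (exact p = 0.0357, 0.9 and 0.0357). FCN1, a marker of monocytes, was found in 1.80% ± 1.12, 0.918% ± 1.09 and 1.98% ± 0.682 (exact p = 0.321, 0.3 and 0.857).

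T-like cells, which should lack these transcripts, gave the background from free RNA at the same 1500 UMIs. There SPP1 was found in 5.48% ± 2.3 of lower lobe, 0.572% ± 0.355 of normal and 1.13% ± 1.11 of upper lobe cells, and FABP4 in 1.03%, 8.23% ± 6.60 and 4.24%. MERTK was found in 0.211%, 0.211% and 0.0859% of T-like cells. FCN1 was found in 0.0448% of lower lobe and 0.105% of normal T-like cells and in 0 of 937 upper lobe cells, which allows up to 0.320%. Before thinning, the median depth per library of macrophage-like cells was 8366 to 12534 UMIs in the lower lobe, 5191 to 12713 in normal lung and 12443 to 24587 in the upper lobe, and that of T-like cells was 2098 to 2850, 1924 to 2319 and 2014 to 3868. Thinning left out 134 (3.29%), 158 (3.89%) and 73 (2.01%) of the macrophage-like cells. Without thinning, the SPP1 shares were 77.6%, 7.31% and 30.1%, the MERTK shares 33.5%, 7.34% and 14.7%, the FABP4 shares 15.6%, 69.4% and 64.7% and the FCN1 shares 6.53%, 2.64% and 9.75%.

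Cycling cells, with transcripts of at least 3 of 15 cell cycle genes, made up 2.41% ± 0.602 (n = 5) of lower lobe, 0.401% ± 0.301 (n = 3) of normal and 2.22% ± 0.499 (n = 3) of upper lobe macrophage-like cells. The exact permutation p was 0.0357 for lower lobe against normal (adjusted p = 0.107), 0.1 for upper lobe against normal (0.15) and 0.5 between the lobes (0.5). These shares rested on 1 cluster, number 17, whose macrophage-like name came from a rule set after the clusters were seen. Without it 0 of 3723 lower lobe, 0 of 3853 normal and 0 of 3332 upper lobe cells were cycling. In cluster 17 all 10 macrophage markers were detected, with a mean log2 fold of 1.02 against all other cells, and monocyte markers, the next type, were at -0.61. In T-like cells 0 of 1936 lower lobe (allowing up to 0.155%), 0 of 954 normal (up to 0.314%) and 0 of 937 upper lobe cells (up to 0.320%) were cycling. This is no background for the macrophage-like share, because the clustering set cycling lymphocytes apart in cluster 32, which was left unnamed and held 58 cells over all libraries. Without thinning the macrophage shares were 5.97%, 1.11% and 6.44%.

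**Figure D3:**
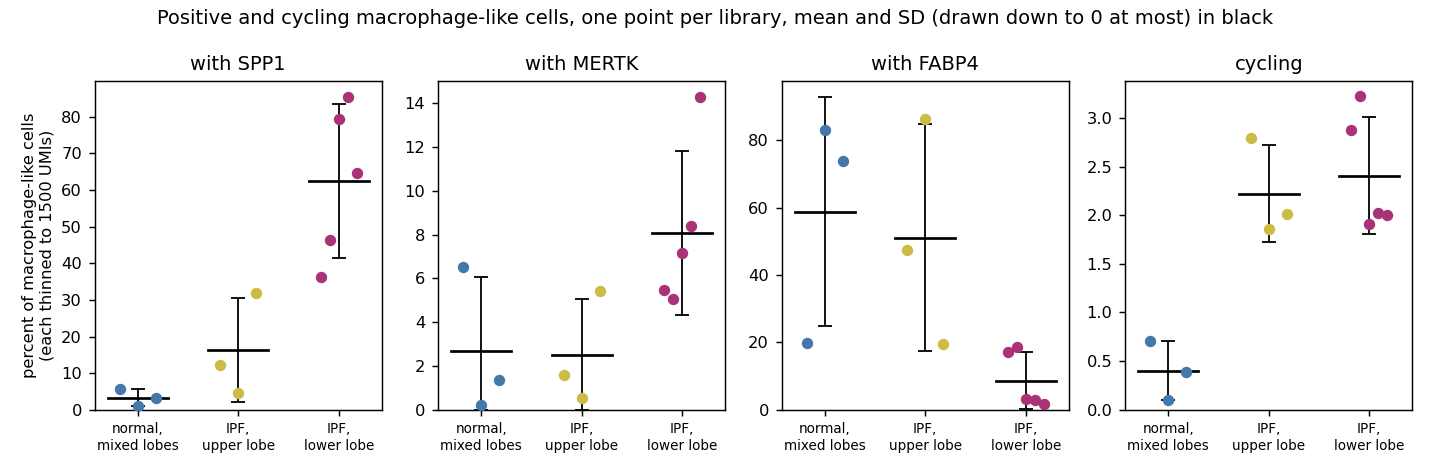
Percent of macrophage-like cells with an SPP1, MERTK or FABP4 transcript and percent cycling, after thinning to 1500 UMIs, with 1 point per library and each group's mean and SD. The mean SPP1 share was 3.32% in normal lung, 62.4% in the IPF lower lobe and 16.2% in the IPF upper lobe.

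Within IPF libraries, macrophage-like cells rich in SPP1 differed from those without it in matrix and antigen presentation genes. MMP7 rose by a log2 change of 4.20 ± 0.26 (7 libraries, paired), from 20.5 to 378 CPM, and the chemokines CCL7 (2.94 ± 0.21) and CCL2 (2.10 ± 0.21) rose with it. FABP4 fell by 3.68 ± 0.32 on the log2 scale, from 918 to 61.3, lower in 6 of 7 libraries. The complement genes C1QA (-1.42 ± 0.10) and C1QB (-1.28 ± 0.09) fell. MERTK was at 52.8 against 46.0 CPM, higher in 5 of 7 libraries, and its change of 0.13 ± 0.21 did not pass (adjusted p = 0.872). MMP9 (2.60), CHI3L1 (2.20), TM4SF19 (2.15), MATK (1.79), TIMP3 (1.63), IL1RN (1.32) and SDC2 (1.15) rose, with LGMN (0.85) and TREM2 (0.36). SERPING1 (-2.21), ALDH2 (-1.64), CES1 (-1.55), PDK4 (-1.52), PLA2G16 (-1.47), CXCL5 (-1.41), THBS1 (-1.32), INHBA (-1.31), AKR1C3 (-1.28), PPARG (-0.62), CCL18 (-0.39) and APOE (-0.27) fell. SPARC (0.01), GPNMB (0.22), MARCO (-0.25) and MRC1 (-0.31) did not pass.

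Among these lists, 6 of 6 MHC class II genes fell (adjusted p = 1.22e-22; 0.00159 with an estimated correlation) and 10 of 18 matrix genes rose while 2 fell (2.74e-12; 0.00159 with an estimated correlation). Of 22 SPP1/MERTK genes 12 rose and 2 fell (1.11e-17; 0.0134 with an estimated correlation), which is not independent evidence because the cells were chosen by SPP1. Of 15 resident macrophage genes 9 fell (5.72e-13, adjusted p = 0.0695 with an estimated correlation), and of 17 heat shock genes 4 fell (0.000772, adjusted p = 0.107 with an estimated correlation). Of 16 lipid genes 4 rose and 2 fell (0.0193, adjusted p = 0.0803 with an estimated correlation), and of 15 unfolded protein response genes 2 rose (0.0235, adjusted p = 0.107 with an estimated correlation). The lists for the cell cycle (0.991), monocyte-derived macrophages (0.0803), growth factors (0.268), interferon (0.539), cytokines (0.557) and oxidative phosphorylation (0.287) did not pass. The test called 303 of 2992 genes, 126 higher and 177 lower, from 1361 SPP1-high and 3816 SPP1-none cells. Of those, 188 moved one way in all 7 libraries, and of the 27 calls of the naming rule 14 held under every alternative run. These p-values take libraries of 3 lungs as separate and are too small. Cycling cells made up 1.63% ± 1.21 of SPP1-high (29 of 1376) and 2.57% ± 1.10 of SPP1-none cells (112 of 4690), a difference of -0.937 percentage points, lower in 6 of 8 libraries (exact 2-sided sign-flip p = 0.203, with 0.0078 the smallest possible). Without thinning this difference reversed, so its direction depends on depth.

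T-like cells of the IPF lower lobe changed 33 of 6559 genes, 18 higher and 15 lower, with 8 to 51 when 1 library was left out. Of the 9 calls of the naming rule 1 held under every alternative run, and those of CD27 and BTN3A2 did not. CD27, a costimulatory receptor of lymphocytes, rose by a log2 change of 1.57 ± 0.30 (5 against 3 libraries, adjusted p = 0.0255), and BTN3A2, a butyrophilin seen by gamma delta T cells, rose by 2.44 ± 0.42 (adjusted p = 0.0157). RARRES3 (1.14) and SLPI (2.47) rose; SLPI is an airway secretory product, and 2 of 4 secretory markers also rose in these cells, at 1036 against 222 CPM, as did 1 of 2 basal markers. Fibroblast markers (106 against 15.1 CPM) were higher too, and 0 of 6 passed. The erythroid marker (205 against 4.98 CPM) and plasma markers (344 against 57.4 CPM) were also higher without passing. ZNF90 (-1.96), NACA2 (-1.82), NBEAL1 (-1.68) and GPR65 (-1.02) fell. ZNF90, NACA2 and NBEAL1 were also lower in single-lobe than in mixed-lobe normal T-like cells. Without TMM scaling, NACA2 was at 135 CPM in mixed-lobe normal, 28.5 in single-lobe normal and 31.9 in IPF lower lobe libraries. In the same order NBEAL1 was at 747, 207 and 199, and ZNF90 at 194, 73.9 and 42.5. The exhaustion and residency list rose (adjusted p = 0.000429; 0.0325 with an estimated correlation) with 0 members passing and 2 adjusted over the list alone. Heat shock genes (0.00385, adjusted p = 0.525 with an estimated correlation), among them HSPA1B (2.81), and MHC class II genes (0.0121, adjusted p = 0.575 with an estimated correlation) rose as lists, and the unfolded protein response fell (0.00569, adjusted p = 0.525 with an estimated correlation). The cytotoxic list did not pass in the lower (0.866) or upper lobe (0.949). In the upper lobe 1 gene passed, the uncharacterised AC004556.1, and the MHC class II (0.0414, adjusted p = 0.489 with an estimated correlation) list rose while the unfolded protein response list fell (0.0436, adjusted p = 0.489 with an estimated correlation). Monocyte markers in upper lobe T-like cells were at 189 against 46.2 CPM, the dendritic marker at 241 against 144 and fibroblast markers at 60.6 against 15.1, and none of them passed. The class held almost only clusters 0 and 2 in each group, and lower lobe p-values are too small for the reason given for macrophages.

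Vascular endothelial-like cells of the IPF lower lobe gained COL15A1, a basement membrane collagen, by a log2 change of 3.45 ± 0.64 (5 against 3 libraries, adjusted p = 0.0419), from 11.5 ± 6.43 to 114 ± 40.7 CPM. COL15A1 (ENSG00000204291) lies on chromosome 9 from 98943179 to 99070792. CD200, an inhibitory surface ligand, rose by 3.37 ± 0.45 (adjusted p = 0.0101), and the insulin receptor INSR by 2.63 ± 0.37 (adjusted p = 0.0131). RP11-536O18.1 (6.42) and CTHRC1 (3.19) rose, and ABI3BP (-2.71), PTGIS (-2.57), GCHFR (-2.07) and CHPT1 (-2.07) fell. The angiogenic and venous list rose with 3 members passing and 5 adjusted over the list alone (adjusted p = 9.67e-06, adjusted p = 0.056 with an estimated correlation), among them SPRY1 (2.65). The fibrillar and basement membrane matrix list rose with 3 members, such as COL6A2 (2.87), and 4 adjusted over the list alone (3.81e-05, adjusted p = 0.325 with an estimated correlation). Cell cycle genes fell as a list (9.67e-06, adjusted p = 0.325 with an estimated correlation), with BIRC5 (-3.34) and TK1 (-2.50) falling, and MHC class II rose (0.000186, adjusted p = 0.325 with an estimated correlation). Fibroblast markers in these cells were at 75.8 against 21.7 CPM, a median log2 change of 1.87, and 0 of 6 passed in a test that recovered 49.5% of simulated 4-fold changes. Of the other markers, 2 of 4 secretory (573 against 124 CPM) and 1 of 6 ciliated rose. Macrophage markers were at 233 against 1102 CPM, a median log2 change of -2.10, and 1 of 10 fell. The normal replicates 1 to 3 held 28, 241 and 159 vascular endothelial-like cells. The test called 97 of 10592 genes, 47 higher and 50 lower, and another grouping of the same libraries called 169. It called 7 to 220 when 1 library was left out and 0 with lower lobe libraries 1 and 2, and 3 and 4, summed, so that none of the 13 calls of the naming rule held under every alternative run. Cluster 36 held 44.3% of lower lobe and cluster 29 held 43.9% of normal cells of the class. At Leiden resolution 0.7, 1 vascular endothelial-like cluster of 1105 cells drew 47.9% of them from lower lobe replicate 3. Such pooled shares can therefore rest on few libraries. Lower lobe p-values are too small. In the upper lobe 1 gene passed, AC004556.1, and the angiogenic (2.61e-05, adjusted p = 0.0962 with an estimated correlation) and matrix lists (9.18e-07, adjusted p = 0.359 with an estimated correlation) rose. The cell cycle (2.1e-05, adjusted p = 0.444 with an estimated correlation) and heat shock lists (0.0142, adjusted p = 0.619 with an estimated correlation) fell there. Macrophage markers in these upper lobe cells were at 264 against 1102 CPM, T markers at 1533 against 586, NK markers at 50.2 against 11.3 and fibroblast markers at 46.1 against 21.7, and none of them passed.

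Monocyte-like cells carried more CXCL10, a chemokine induced by interferon, in both IPF lobes. CXCL10 (ENSG00000169245, chromosome 4, 76021117 to 76023497) rose by a log2 change of 4.95 ± 0.84 in the lower lobe (5 against 3 libraries, adjusted p = 0.00894) and 6.05 ± 0.89 in the upper lobe (3 against 3, adjusted p = 0.00938). SPP1 rose in the lower lobe by 5.51 ± 0.72 (adjusted p = 0.00159), from 84.5 ± 25.9 to 3849 ± 2695 CPM, and the monocyte attractant CCL7 rose in the lower (5.85) and upper lobe (5.19). AC004556.1, an uncharacterised transcript, rose in the lower (6.67) and upper lobe (6.54). In the lower lobe PDK4 (-2.55), CYP1B1 (-3.91), NHSL2 (-2.37) and ZNF90 (-2.22) fell, and in the upper lobe GBP5 (3.97) rose and ZNF90 (-2.16), NBEAL1 (-2.15), NACA2 (-2.12) and NHSL2 (-2.11) fell. ZNF90, NBEAL1 and NACA2 were also lower in single-lobe than in mixed-lobe normal monocyte-like cells. The interferon list rose in the upper lobe with 3 members, GBP1 (3.91) among them, and 11 adjusted over the list alone (adjusted p = 6.61e-13, adjusted p = 0.219 with an estimated correlation). It rose in the lower lobe with CXCL10 alone (0.00578, adjusted p = 0.757 with an estimated correlation). In the upper lobe cytokines (3.23e-06, adjusted p = 0.219 with an estimated correlation), with NFKBIZ (-1.66) falling, and the cell cycle (0.0159, adjusted p = 0.219 with an estimated correlation) fell as lists, and the unfolded protein response list rose (0.00524, adjusted p = 0.517 with an estimated correlation). The test called 157 of 7719 genes in the lower lobe, 89 higher and 68 lower, and 69 in the upper lobe, 40 higher and 29 lower. With 1 library left out these were 60 to 242 and 12 to 231, and 4 of 9 and 2 of 11 calls of the naming rule held under every alternative run, CXCL10 in both lobes among them. With lower lobe libraries 1 and 2, and 3 and 4, summed, which leaves fewer samples, the lower lobe count fell below its range. A fit over only the groups compared called 12 in the upper lobe. The line between monocyte-like and macrophage-like cells depended on the clustering. At Leiden resolution 0.7, monocyte (mean log2 fold 0.761) and macrophage markers (0.646) led alike in an unnamed cluster of 5054 cells. In the main clustering, clusters 4 and 9 held 55.0% and 44.2% of the monocyte-like class in the lower lobe, 34.8% and 63.7% in the upper lobe and 52.5% and 46.8% in normal lung. Macrophage markers were lower, with 4 of 10 falling in the lower and 1 of 10 in the upper lobe. In the lower lobe 2 of 4 secretory (699 against 150.3 CPM), 1 of 3 basal and 1 of 2 ciliated markers rose and 1 of 4 AT2 markers fell. In the upper lobe the erythroid marker was at 394 against 1.92 CPM and did not pass, and lower lobe p-values are too small.

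Fibroblast-like cells gained POSTN, a matrix protein of scar tissue, in both IPF lobes. POSTN (ENSG00000133110, chromosome 13, 37562583 to 37598844) rose by a log2 change of 6.90 ± 1.05 in the lower lobe (5 against 3 libraries, adjusted p = 0.0102), from 6.57 ± 11.4 to 880 ± 644 CPM, and by 6.56 ± 1.06 in the upper lobe (3 against 3, adjusted p = 0.0243). Its normal level had an SD above its mean, so the size of these changes is uncertain. The normal libraries held 35, 55 and 58 fibroblast-like cells, against 97 to 670 in the lower and 39 to 205 in the upper lobe. COMP, a cartilage matrix protein, rose by 6.39 ± 1.01 in the lower lobe (adjusted p = 0.0111). CHN1 rose in the lower (5.47) and upper lobe (4.61), COL15A1 (4.66) in the lower lobe, and SYNPO (2.93) and ASPN (2.77) in the upper lobe. PTX3 (-5.46), CXCL8 (-4.57), CYP4B1 (-4.40) and CHI3L2 (-4.02) fell in the lower lobe, and NACA2 (-2.51), INSIG1 (-2.33), NBEAL1 (-2.01) and ZNF90 (-1.92) in the upper lobe. NACA2, NBEAL1 and ZNF90 were also lower in single-lobe than in mixed-lobe normal fibroblast-like cells. The matrix list rose in the lower lobe (adjusted p = 8.36e-06, adjusted p = 0.442 with an estimated correlation) with 3 members, such as COL6A3 (1.31), and in the upper lobe (3.6e-08, adjusted p = 0.359 with an estimated correlation) with 1. The contractile list rose in the lower (9.83e-05, adjusted p = 0.404 with an estimated correlation) and upper lobe (1.75e-08, adjusted p = 0.232 with an estimated correlation), in both with 6 members adjusted over the list alone. Smooth muscle or pericyte markers moved with that list, from 686 CPM to 1787 in the lower lobe (median log2 change 1.51) and 2578 in the upper lobe (1.77), and 0 of 6 passed. Cytokines fell in the lower lobe (6.7e-09, adjusted p = 0.268 with an estimated correlation), with CCL20 (-4.48) and IL1B (-4.43) falling, and in the upper lobe (8.23e-08, adjusted p = 0.232 with an estimated correlation). MHC class II fell in the lower lobe (2.86e-06, adjusted p = 0.268 with an estimated correlation), and the cell cycle (0.0372, adjusted p = 0.407 with an estimated correlation) and heat shock lists (0.0372, adjusted p = 0.592 with an estimated correlation) fell in the upper lobe. With a minimum of 50 cells per library that cell cycle list pointed up (0.794). Macrophage markers were at 227 against 2417 CPM in the lower lobe, with 3 of 10 falling, as did 1 of 3 T and 1 of 4 AT2 markers, while 2 of 4 secretory markers rose (908 against 90.0 CPM). The test called 210 of 9482 genes in the lower lobe, 83 higher and 127 lower, and 18 in the upper lobe, 10 higher and 8 lower. With 1 library left out these were 101 to 218 and 1 to 24, and a fit over only the groups compared called 0 in the upper lobe. With lower lobe libraries 1 and 2, and 3 and 4, summed, which leaves fewer samples, the lower lobe count fell well below its range. Under every alternative run 3 of 11 lower lobe calls of the naming rule held, POSTN and COMP among them, and 0 of 8 upper lobe calls. Cluster 16 held 64.6% of the class in the lower lobe, 76.9% in the upper lobe and 57.4% in normal lung, and lower lobe p-values are too small.

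Among cells kept from at least 1000 UMIs, 10 of the cell classes differed between the IPF lower lobe and normal lung at the smallest exact permutation p possible, 0.0357, and none of 48 tests passed after adjustment (smallest adjusted p = 0.132). Fibroblast-like cells were 10.6% ± 4.60 (SD, n = 5) in the lower lobe against 1.51% ± 0.408 (n = 3), vascular endothelial-like cells 13.4% ± 5.64 against 4.22% ± 2.93, and basal airway-like cells 5.81% ± 5.47 against 0.0375%. Mast (4.20% against 0.881%), secretory airway (5.08% against 0.385%) and smooth muscle or pericyte-like cells (2.17% against 0.459%) were also at higher shares. NK-like cells were 1.35% ± 1.24 against 9.56% ± 4.02, monocyte-like cells 4.88% ± 1.56 against 15.6% ± 4.13, AT2-like cells, the source of surfactant, 0.295% ± 0.240 against 5.17% ± 2.93, and AT1-like cells 0.0310% against 0.570%. The AT1-like difference depended on the clustering and reversed at Leiden resolution 0.7, to a higher share in the lower lobe. The cluster named AT1-like held 1628 cells over all libraries at that resolution, against 208 in the main clustering. Macrophage-like cells were 21.6% ± 8.67 in the lower lobe, 36.7% ± 6.95 in the upper lobe and 42.4% ± 14.4 in normal lung (exact p = 0.0714 for lower and 0.6 for upper lobe against normal). Between the lobes, NK-like (7.48% ± 1.76 in the upper lobe), AT2-like (3.48% ± 2.46) and basal-like cells (0.622%) differed at exact p = 0.0357. Outside the comparisons, the normal upper lobe library had 1.64% NK-like, 10.5% vascular endothelial-like, 5.78% fibroblast-like and 1.54% secretory airway-like cells. Each of these lay inside the range of the 5 lower lobe libraries. For the other classes that differed against normal it lay outside, as did the normal lower lobe library for all 10. Shares of a total move together, and the unnamed clusters held 5.72% of lower lobe, 2.40% of upper lobe and 0.600% of normal cells.

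**Figure D4:**
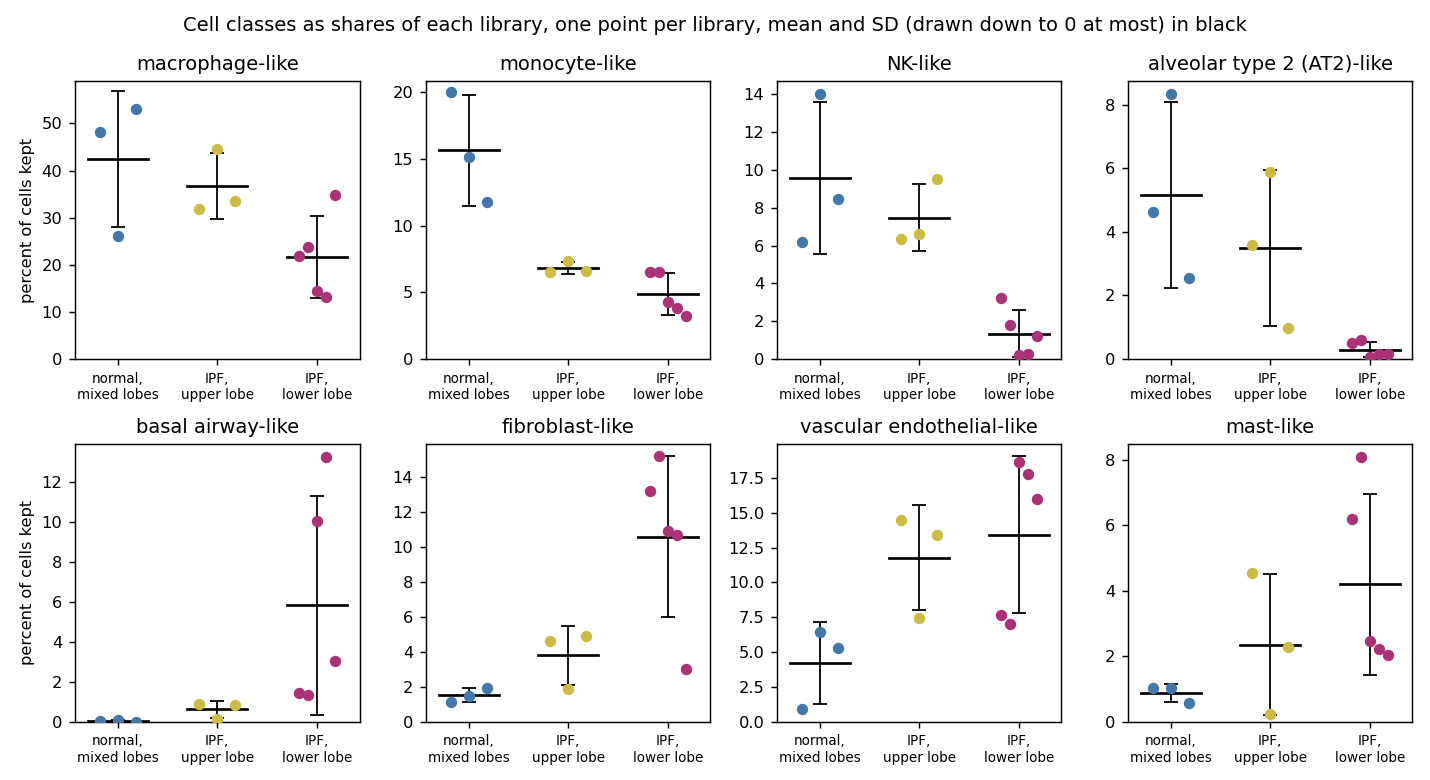
Percent of all kept cells in 8 cell classes, with 1 point per library and each group's mean and SD. NK-like cells averaged 1.35% in the IPF lower lobe, 7.48% in the IPF upper lobe and 9.56% in the normal libraries compared. The single-lobe normal libraries, not drawn, had 4.03% (lower lobe) and 1.64% (upper lobe).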

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

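No test in this part was chosen after its result was seen. Among the 5 IPF lower lobe libraries, 9 values lay far from the other 4 libraries of 152 groups of values checked, and chance gives about 1 in 20 such groups, so these may be chance. In lower lobe replicate 2, macrophage-like cells had 887 CPM of CHI3L1 (the others 144 to 306), 343 of MMP9 (72.0 to 83.5), 121 of A2M (91.1 to 95.4) and 339 of LILRB4 (187 to 216). In the same library fibroblast-like cells had 7.72 of CCL20 (0.958 to 1.82). In lower lobe replicate 5, macrophage-like cells had 154 of SDS (36.7 to 63.0), 1.97 of GLDN (17.9 to 21.1) and 39.0 of MATK (67.2 to 76.6), and T-like cells had 6.74 of NACA2 (35.7 to 45.2). Without lower lobe replicate 2, 1370 genes passed in macrophage-like cells against normal, and 1712 with it. No explanation was tested for these values.

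Between the lower and upper lobe of IPF lungs, 7 gene lists differed in macrophage-like cells by camera at its preset correlation, and none did with an estimated correlation. The SPP1/MERTK list (8.16e-09, against 0.0971 with the estimated correlation), the phagocyte matrix list (6.67e-08, 0.0971), the inflammatory cytokines (0.000173, 0.0971) and the heat shock list (0.0232, 0.511) were higher in the lower lobe. Resident macrophage genes (3.76e-10, 0.176), cholesterol synthesis (0.0232, 0.657) and interferon genes (0.0213, 0.657) were lower. All values are adjusted p-values over 5 against 3 libraries, and no single gene passed.

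In libraries outside the comparisons, 3 shares had a 95% interval wholly above the intervals of all 3 normal libraries compared, each counted after thinning to 1500 UMIs. Shares above those libraries with intervals that overlapped, such as cycling cells in the single-lobe normal libraries, are not among the 3. FABP4 was found in 87.8% of macrophage-like cells of the normal lower lobe library (766 of 872; 95% Clopper-Pearson interval 85.5 to 89.9), against 19.8% to 83.0%. FCN1 was found in 7.90% of macrophage-like cells of the normal upper lobe library (155 of 1961; 6.75 to 9.19), against 0% to 2.12%. SPP1 was found in 20.4% of monocyte-like cells of the normal lower lobe library (290 of 1424; 18.3 to 22.6), against 3.37% to 5.79%. The intervals cover counting error only and not the spread between libraries. For FABP4 that spread was an SD of 34.1 percentage points over the 3 normal libraries compared, and 1 IPF upper lobe library reached 86.3%. Each of the 3 shares is 1 library, so no test was possible, and no biological explanation was tested.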

How the results depend on the processing

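Alternatives that summed or averaged lower lobe libraries 1 and 2, and 3 and 4, left out the cluster led by cell cycle genes, thinned a second time, or added single-lobe normal libraries to shares were chosen after the data were seen. No paired analysis was possible because the labels tie no library to a lung. With processing alternatives, 2088 of 2365 values of named genes, 1226 of 1355 of lists, 229 of 253 of shares and 90 of 144 counts of genes kept their direction and side of the threshold, or for counts stayed within 1.5 times. With 1 library left out these were 1487 of 1937, 1150 of 1265, 222 of 230 and 69 of 128. For shares this is agreement of direction only, because with so few libraries no share could pass after adjustment. The exceptions were the paired cycling test and the alternative that added single-lobe normal libraries, where the side of the threshold could change. Of 162 named gene calls, 50 held under every alternative run and 112 were lost under at least 1, 89 of them when 1 library was left out. In macrophage-like cells of the lower lobe 26 of 51 calls held throughout, SPP1, CHI3L1, MMP7 and TREM2 among them, and in the upper lobe 0 of 23. For the results that changed below, the cause was not tested except where fewer samples or genes are part of the alternative.

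Counts of genes against normal moved as follows. DESeq2 called 671 in macrophage-like upper lobe cells, 275 between the lobes, 71 in T-like upper lobe, 392 and 78 in vascular endothelial-like lower and upper lobe, 297 and 200 in monocyte-like, and 488 and 157 in fibroblast-like cells. Without a filter on low counts the counts were 131 in macrophage-like upper lobe cells, 64 between the lobes, 202 and 100 in T-like lower and upper lobe, 301 and 47 in vascular endothelial-like, 619 and 434 in monocyte-like, and 488 and 116 in fibroblast-like cells. With single-lobe normal libraries added they were 27 in macrophage-like and 5 in T-like upper lobe, 204 and 11 in vascular endothelial-like, 97 and 27 in monocyte-like, and 573 and 94 in fibroblast-like cells. A fit over only the groups compared gave 0 in macrophage-like, T-like, vascular endothelial-like and fibroblast-like upper lobe, 12 in monocyte-like upper lobe, and 10 between the lobes. With libraries 1 and 2, and 3 and 4, summed, which leaves fewer samples, they were 475 and 9 in macrophage-like lower and upper lobe, 8 in T-like lower lobe, 0 and 0 in vascular endothelial-like, 23 and 28 in monocyte-like, and 27 and 11 in fibroblast-like cells. Choices of 3 of the 5 lower lobe libraries gave 360 to 988 in macrophage-like cells. At 2000 UMIs per cell the count was 7 in T-like and 29 in fibroblast-like upper lobe. Leiden resolution 0.7 gave 2 between the lobes, and 61 and 2 in T-like cells. Keeping doublets gave 157, and a minimum of 50 cells 37, in vascular endothelial-like lower lobe. Macrophage-like and monocyte-like cells summed gave 175 in the upper lobe, and leaving out the cycling cluster gave 48 there. SPP1-high against SPP1-none cells gave 60 without the library block. With an estimated correlation 1 of 45 list tests passed in macrophage-like cells and 1 of 70 in the other classes.

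Without cluster 17, which held every cycling macrophage-like cell, no cycling share could be compared. MKI67, TOP2A and RRM2 then had too few counts to be tested, the log2 change of TYMS was 0.92 and no longer passed, TK1 still passed at 1.54, and the cell cycle list still passed at the preset correlation in the lower (adjusted p = 0.0307) and upper lobe (0.0283). With an estimated correlation the list with cluster 17 had not passed in the lower (0.347) or upper lobe (0.205).

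Shares, in percentage points, moved as follows. With single-lobe normal libraries added, 6 of 48 class shares passed, all lower lobe against normal: AT1-like -0.827, AT2-like -3.99, basal-like 5.77, mast-like 3.04, monocyte-like -14.4 and smooth muscle or pericyte-like cells 1.74. The SPP1 share (59.4), the FABP4 share (-61.5) and cycling cells in the lower (1.52) and upper lobe (1.34) also passed then, since more libraries allow smaller exact p-values. With them the 5 normal libraries came from 4 lungs and the 5 lower lobe libraries from 3, so all of these p-values are too small. The FCN1 share reversed to -0.926 in the lower and -0.746 in the upper lobe, and the MERTK share in the upper lobe to 0.849. That MERTK share also reversed at 2000 UMIs per cell (0.150), resolution 0.7 (1.11), thinning to 3000 UMIs (0.359) and unthinned (7.36). The FCN1 share between the lobes reversed at resolution 0.7 (0.373) and thinned to 1000 UMIs (0.290). Cycling between the lobes reversed at resolution 0.7 (-0.212), thinned to 3000 UMIs (-0.184) and unthinned (-0.466), and cycling in SPP1-high against SPP1-none cells unthinned (2.04). AT1-like cells reversed at resolution 0.7 (5.60). Among genes that had not passed, MARCO reversed at resolution 0.7 (-0.092) and FCN1 with single-lobe normal libraries (-0.75). In SPP1-high cells SPARC reversed without a filter (-0.050), at 2000 UMIs (-0.0016), at resolution 0.7 (-0.050) and in the lower lobe alone (-0.043), and MERTK at resolution 0.7 (-0.27) and in the lower lobe alone (-0.018). The cell cycle list in fibroblast-like upper lobe cells, which had passed, reversed with a minimum of 50 cells (adjusted p = 0.794).

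Leaving out 1 library at a time (N normal, L lower lobe and U upper lobe replicate) gave 793 to 2226 genes in macrophage-like lower lobe cells, with 793 without N2, 838 without N3, 970 without L3 and 972 without L4. In the upper lobe it gave 9 to 226: N1 226, N2 11, L1 37, U1 10, L2 47, L3 33, L4 26 and U3 9. Between the lobes it gave 0 to 7: N1 7, N3 5 and U1 1. T-like lower lobe cells ranged from 8 to 51 (N2 8, L1 15, L3 16, U2 51, L4 16) and upper lobe cells from 1 to 7 (N1 7, N3 5). Vascular endothelial-like lower lobe cells ranged from 7 to 220 (N1 37, N3 7, L1 53, L2 30, L3 12, U2 220, L4 9, L5 14, U3 28) and upper lobe cells from 0 to 21 (N2 21, N3 0, U1 0, U2 12, U3 0). Monocyte-like lower lobe cells ranged from 60 to 242 (N2 242, N3 60, L1 69, L2 101, L4 67) and upper lobe cells from 12 to 231 (N1 31, N2 231, N3 17, L1 42, U1 39, L2 44, L3 37, U2 12, L4 42, U3 24). Fibroblast-like lower lobe cells ranged from 101 to 218 (N3 130, L1 123, L3 103, L4 101) and upper lobe cells from 1 to 24 (N3 1, U1 11, U3 1). SPP1-high cells ranged from 189 (without L1) to 313.

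The difference in MERTK share between upper lobe and normal ranged from -1.64 to 1.72 percentage points (N1 1.72, U1 0.279, U2 0.792 reversed) and that in FABP4 share from -27.2 to 8.09 (N2 4.36, U3 8.09 reversed). Between the lobes the FCN1 share ranged from -0.536 to 0.187 (U1 0.187, L5 0.179) and cycling from -0.0188 (L2) to 0.469. The metallothionein list in the upper lobe ranged from adjusted p = 4.6e-05 to 0.247 and reversed without N2. In the lower lobe MT1M ranged from -4.49 to 0.76 (N2 0.76), MARCO from -0.082 to 0.32 (N3 -0.082, L5 -0.03) and CCL18 from -0.10 (N3) to 1.68. In the upper lobe MERTK ranged from -1.29 to 2.73 (N2 -0.13, N3 -0.11, U3 -1.29) and FABP4 from -1.06 to 0.30 (N2 0.30, U3 0.13). In SPP1-high cells SPARC ranged from -0.18 to 0.21 (L2 -0.18, U3 -0.04) and MERTK from -0.0087 (U3) to 0.37. Depth limits the rarer shares: a count of 0 among 937 T-like cells still allows a share of up to 0.320%.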

Other observations

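The tests of partial copies, of runs and of IPF as the whole cause below, and those of cycling cells, were chosen after their results were seen. In the libraries outside the comparisons, SPP1 was found in 3.56% (95% Clopper-Pearson interval 2.43 to 5.01) of macrophage-like cells of the normal lower lobe library and 1.78% (1.25 to 2.47) of the normal upper lobe library, after thinning to 1500 UMIs. MERTK was found in 0 of 872 cells (allowing up to 0.344%) and in 0.204% (0.0556 to 0.521). Cycling cells were 1.83% (1.05 to 2.96) and 1.38% (0.909 to 2.00), all in cluster 17. In fresh lavage SPP1 was found in 0.330% (0.0400 to 1.19) and FABP4 in 77.7% (74.2 to 81.0) of 606 cells, and in frozen lavage in 3.01% (1.90 to 4.52) and 45.3% (41.6 to 49.0) of 731 cells. The 3 version 1 libraries, which came from 2 lungs, had SPP1 in 6.71% ± 5.85 (SD over libraries) and FABP4 in 44.9% ± 20.9.

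The same genes fell in several IPF cell classes: 15 genes fell in at least 3 of the 5 classes, among them NACA2, NBEAL1, ZNF90, UQCRHL, PABPC3 and H3F3C, each with an abundant partner such as NACA, RPL12 or RPS16. Of these genes 46.7% (7 of 15) shared at least 80 sequences of 21 bases with an abundant gene, against 179 of 9086 other genes (Fisher's exact p = 7.46e-09). At least 20% of their sequences were shared by 20% (3 of 15), against 20 of 9086 other genes. That share lay between the limits set beforehand, so it was left undecided. Of the 15 genes, 9 shared at least 45 such sequences and were also lower in single-lobe than in mixed-lobe normal macrophage-like cells. Their median was -1.96 on the log2 scale, against -2.19 in the IPF lower lobe, which argues against IPF as the whole cause for these 9 genes. Both single-lobe libraries came from 1 lung. The genes were also chosen as high in the same mixed-lobe libraries, which by itself favours lower levels elsewhere. A difference in library preparation or sequencing between the mixed-lobe normal libraries and the others may account for this fall. These values cannot tell it from the effect of that choice. Near-identical copies outside the set had a median log2 gap to all genes of -0.738 over 17 genes, which leaves a trend over every copy open. In the other direction 10 genes rose in at least 3 classes, among them AC004556.1 and the secretory airway markers BPIFB1 and SCGB3A1 in 5 of 5, and no explanation was tested for these.

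Outside macrophage-like cells SPP1 passed only in monocyte-like cells of the lower lobe. In the lower lobe its log2 change was 2.71 in T-like (adjusted p = 0.0912), 3.80 in vascular endothelial-like (0.119) and 2.89 in fibroblast-like cells (0.153), and in the upper lobe 2.49 in monocyte-like (0.0866), 0.47 in T-like (0.894), 1.75 in vascular endothelial-like (0.729) and -0.17 in fibroblast-like cells (0.992). In T-like cells its ratio to macrophage-like cells lay within 3 times that of macrophage markers in 8 of 8 IPF libraries (0.545 to 2.33 times), so free RNA from macrophages may be its source there. In vascular endothelial-like cells this held in 2 of 8 libraries (1.20 to 27.6 times), with SPP1 above every marker in 7, which argues against free RNA as its whole source there. In the lower lobe alone, where SPP1 was higher, the ratio was only 1.20 to 4.34 times, and SPP1 was also above every marker in normal replicate 1, so the part of free RNA in the lower lobe rise stays open. In monocyte-like cells SPP1's ratio was 16.9 to 319 times that of the markers in T-like cells, within 3 times in 0 of 8 libraries, which argues against free RNA at the level seen in T-like cells. Against the markers in monocyte-like cells themselves it lay within 3 times in 5 of 8, so macrophages mixed into that class stay open, as does IPF itself, untested.

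Cycling macrophage-like cells were more frequent in IPF. Free RNA is argued against, since 67 of 7487 cells in IPF libraries had at least 5 of the 15 genes after thinning, where random scatter fitted to the cells with at least 2 gives 0.105. Doublets stay open. Keeping the called ones moved the lower lobe difference by -1.03% (from 2.01 to 1.98 percentage points), but this added only 22 of 3956 lower lobe cells, which could have raised it by 27.7% at most. A difference between runs stays open: 0 of 2 single-lobe normal libraries lay inside the IPF range of 1.86% to 3.22%, and 0 inside the mixed-lobe normal range of 0.105% to 0.708%. The naming of cluster 17 also stays open, since all of these cells lay in it, so more cycling macrophages in IPF is a hypothesis that may depend on that name.

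Other groupings of the same libraries tested whether chance could give as many genes. For the lower lobe against normal, 1 of 56 groupings gave as many as the real 1712 in macrophage-like cells (highest other 13), and likewise 33 in T-like (16), 157 in monocyte-like (10) and 210 in fibroblast-like cells (100), a share of 1 in 56. That share takes 5 libraries of 3 lungs as independent, so it is too small and does not exclude chance. With libraries 1 and 2, and 3 and 4, summed, 10 groupings are possible, too few for a share under 0.05, and the counts were 475, 8, 23 and 27. In vascular endothelial-like cells 2 of 56 gave as many as 97, and the highest other gave 169, so the real grouping did not give the most genes. The reason was not tested, and chance stays open there too. Between the lobes the real count was 0 (highest other 11), so 56 of 56 had to give as many and this decides nothing. For the upper lobe against normal there are 10 groupings, too few for a share under 0.05; the real and highest other counts were 74 and 42 in macrophage-like, 1 and 0 in T-like, 1 and 2 in vascular endothelial-like (3 groupings gave as many), 69 and 0 in monocyte-like and 18 and 1 in fibroblast-like cells. For SPP1-high against SPP1-none cells 1 of 64 swaps gave as many as 303 (highest other 62), a share that also takes libraries of 3 lungs as independent and so does not exclude chance.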
